A study of Mus musculus with 9 samples.

How the data were processed

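The data were bulk RNA sequencing profiles of mouse colon, 9 libraries in 3 groups of 3. Per the labels, the mice were wild type, total RNA was purified on RNeasy columns, and libraries followed standard Illumina preparation. Per the submitters' processing notes, bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0 and StringTie 2.1.3b were used with the mouse build GRCm38 (mm10). The strandedness of the libraries, the setting used for counting, any filter on reads and the annotation release were not given in the sources used here. The authors deposited 1 table with 45777 genes and, for each library, a read count, an FPKM and a TPM. The deposited read counts were whole numbers, not normalized, and were the input of the main tests. The deposited FPKM values, which the authors scaled by gene length and library total, entered only alternative tests. The deposited TPM values, which the authors scaled to a common sum per library, were not used in a test. Every per-sample column could be matched to a library, leaving 0 unused.

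Of the gene identifiers, 45679 matched the reference annotation of the same build (GRCm38.p6) and 98 did not. Coordinates are 1-based. A total of 27860 genes had a read, and 18414 passed edgeR's filterByExpr by group (minimum count 10, minimum total count 15) and were tested; 83.3% of these were protein coding. Library totals ran from 19638401 to 42917198 counts. CPM values are given per library on the edgeR effective library size after TMM scaling, and mean levels on the log2 scale used a prior count of 2. A fold against a group with no read was computed against a floor of 3 counts summed over the group, which covers counting error only.

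All 9 libraries entered 1 edgeR 4.0.16 quasi-likelihood fit (robust, current version of the method) with group as the only term, in R 4.3.3. The 3 pairwise contrasts and a test of any difference among the 3 groups were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.469 with 6 residual degrees of freedom. The median standard error of a log2 fold change was 0.37. A total of 52 gene lists, 24 gene groups and 28 cell type or region marker lists, were fixed in advance, and the 51 lists with at least 5 tested members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01. Camera is two-sided and compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether the members of a list move in one direction on balance, were run beside it. The number of members passing when adjusted over the list alone was counted as well. The sex-linked list had 4 tested members and was not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

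The design, the lists, the tests and most alternatives were chosen before the data were examined. These alternatives were relative log expression (RLE) and upper quartile scaling, no filter and a filter of CPM at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, the older form of edgeR's test, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with FPKM of at least 1 in 3 libraries and on log2(FPKM + 1) with no filter, protein-coding genes without immunoglobulin and mitochondrially encoded genes, a fit of only the groups compared, a replicate block, the estimated correlation, camera on voom values, and leaving out each library in turn. Alternatives added after seeing the data were leaving out both CT 2 and IM 3, a covariate for the share of counts on the 18S ribosomal pseudogene Rn18s-rs5, and a covariate for colon position, the mean log2 CPM of 8 distal Hox genes. The upper quartile, filter and protein-coding settings for the gene lists were also added then.

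Named genes followed a rule fixed in advance: up to 12 genes per direction that passed, were separated between the groups and had a mean of at least 1 CPM in the higher group, leaving out unnamed gene models. Where none passed, the 6 with the smallest p per direction were named as not passing. Up to 4 members of a passing list and up to 2 of another list were named. Members of the receptor, tight junction and hormone lists could be named freely.

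The tests were tried on simulated counts drawn from the real means and library sizes, with 200 genes changed. The spread of each gene (its dispersion) was the one edgeR had fitted, the same for all libraries. These draws therefore follow edgeR's model, so false calls of edgeR and DESeq2 on them are not a neutral comparison. In the simulation of IM against CT (18106 genes), edgeR recovered 0 of 67 genes changed 2-fold, 47.8% of those changed 4-fold and 75.8% of those changed 8-fold, with 2 false among 84 calls. For IM-HYA against IM (18118 genes) it recovered 4.48%, 52.2% and 75.8%, with 8 false among 96 calls, and for IM-HYA against CT (18101 genes) 2.99%, 58.2% and 75.8%, with 6 false among 97. DESeq2 made 60 false calls among 177, 46 among 169 and 68 among 194 in the same simulations. A list raised 2-fold was recovered by camera under the preset and the estimated correlation in each simulation, with 0 other lists passing. Genes were drawn independently of one another there, so this cannot show how often lists pass falsely where genes move together. In the real data the median estimated correlation within lists was 0.23 in IM against CT, 0.22 in IM-HYA against IM and 0.23 in IM-HYA against CT. The correlation of the contrasts that share the IM libraries was set beside 100 simulated data sets without group effects and 100 relabellings of the libraries.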

Results

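Colon RNA was sequenced from wild-type mice in 9 libraries, 3 in each of 3 groups. Control mice (CT) ate a normal diet. The IM mice ate that diet and had a hindlimb cast for 10 days, and the IM-HYA mice had the cast on a diet with HYA, which the labels do not spell out. No library came from mice given HYA without a cast, so the effect of the diet could be read among immobilized mice alone. CT libraries held 37820345, 31103554 and 19638401 counts, IM libraries 35662716, 31395448 and 22140783, and IM-HYA libraries 41430849, 42917198 and 34898874. The labels number 3 replicates per group but do not say that each came from its own animal, so p-values here measure the spread between these libraries, which may be technical. All pairs of replicates differed by more than counting noise (chi-square per gene 39.8 or more). Levels below are mean CPM (counts scaled to library size) ± SD over the 3 libraries of a group, and log2 fold changes are given with their standard error (SE).

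The libraries differed in the tissue they held, both within groups and, for some markers, between them. Pancreatic enzyme genes, which the colon does not normally express, took 42.6% of the counts of CT 2, 0.678% of IM 3 and 0.0507% of IM 1. Adipocyte markers were highest in IM 3 and IM 1, at a mean log2 CPM of 6.16 and 4.57, against 2.37 to 3.47 in the other libraries. T cell and B cell markers were also highest in IM 3 (3.25 and 4.70) and then in IM 1 (0.68 and 2.93). Genes that mark position along the colon parted libraries of the same group. Hoxd13, a posterior Hox gene, measured 105, 33.6 and 4.62 CPM in the CT libraries, 99.5, 0.591 and 0 in the IM libraries and 96.0, 3.65 and 105 in the IM-HYA libraries. Hoxb6, a more anterior Hox gene, reached 23.5 CPM in IM 2 and 91.7 in IM 3 and at most 3.83 elsewhere. Muc2, the main secreted mucin of goblet cells, ran from 791 CPM in IM-HYA 3 to 12847 in IM 2. The 18S ribosomal pseudogene Rn18s-rs5 took 2.88% to 23.2% of counts, with all 3 IM-HYA libraries at 4.60% or less. The nearest library belonged to the same group for 3 of the 9 libraries, and the first principal component (40.8% of the variance) set IM 3 apart.

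**Figure D1:**
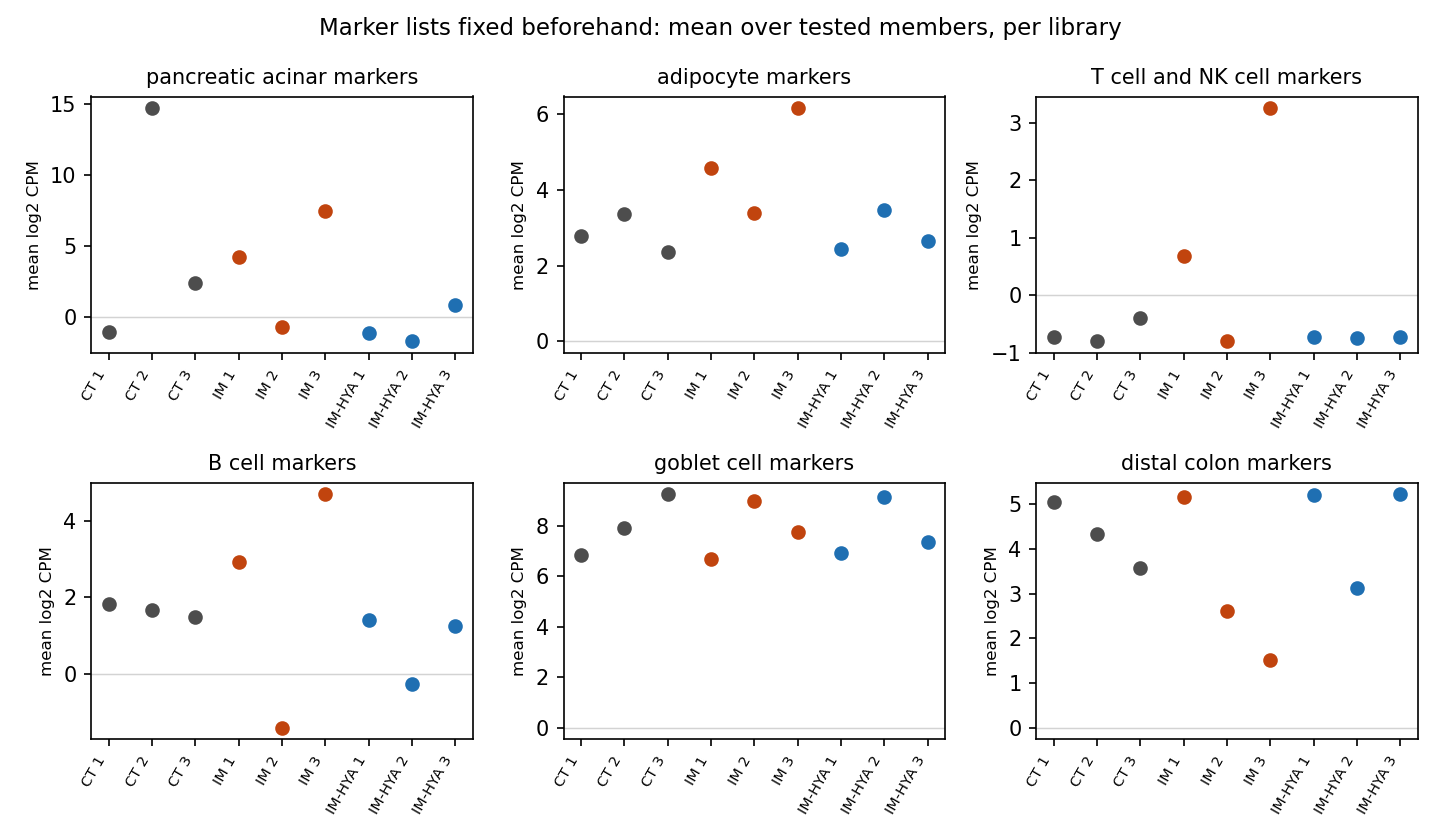
Mean log2 CPM of 6 marker lists (vertical axes) in each of the 9 libraries (horizontal axes), 1 point per library, coloured by group. CT 2 stands apart in pancreatic acinar markers at 14.72, and IM 3 in adipocyte markers at 6.16 and T cell markers at 3.25, while goblet and distal colon markers vary within all 3 groups.

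The comparison of IM with CT asked what immobilization by the cast did to the colon under a normal diet. The long noncoding RNA gene G530011O06Rik (Entrez 654820), chosen after its values were seen because it was the only gene to pass, fell from 19.98 ± 1.13 CPM in CT to 0.829 ± 0.164 in IM (n = 3 each), a log2 fold change of −4.58 (SE 0.33). It measured 0.769 ± 0.236 CPM in IM-HYA. The gene lies on chromosome X, 169975043 to 169978917 (GRCm38), on the minus strand, inside the plus-strand gene Mid1 (169685199 to 170005736). The counting strand was not given in the sources used here, so reads of these overlapping genes cannot be told apart with certainty. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment its adjusted p was 0.00237, and all 3 IM libraries lay below all 3 CT libraries. Over 24 alternatives the adjusted p ran from 8.97e-38 to 0.102 with the fold change always below 0, and the call for the G530011O06Rik log2 fold change, IM vs CT, ended for unfiltered log2(FPKM + 1) values (adjusted p = 0.0882) and without CT 2 and IM 3 together (adjusted p = 0.102).

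No other gene passed in IM against CT. Of 18414 genes tested with edgeR, 0 were called higher and 1 lower, while 890 were higher and 572 lower at an unadjusted p under 0.05 (7.94% of genes). DESeq2 called 65 genes, 52 higher and 13 lower, and made 60 false calls among 177 on counts simulated with edgeR's dispersions. The groups did not overlap for 820 genes higher and 846 lower in IM, 9.05% of genes, where chance gives 10%. edgeR called 2 genes without CT 1 and 2 without IM 2. The count at an unadjusted p under 0.05 was 3811 without IM 1, 2204 without IM 2 and 961 without IM 3.

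The genes with the smallest p that were higher in IM, none passing (edgeR adjusted p = 0.621 for each), included the heat shock protein gene Hsph1 at 16.1 ± 0.766 CPM in CT and 52.4 ± 13.1 in IM, log2 fold change 1.70 (SE 0.29). Cyp4b1, a cytochrome P450, measured 1.65 ± 0.344 and 14.0 ± 10.9 CPM, the carboxylesterase gene Ces1d 25.1 ± 3.81 and 47.3 ± 6.89, and Crybg2 18.8 ± 1.23 and 35.6 ± 5.27. The protocadherin gene Pcdhga3, which shares exons with its cluster neighbours, measured 0.0629 ± 0.109 and 6.57 ± 2.12 CPM. The immunoglobulin segment Ighv1-84 had no read in CT and 202 counts in IM, at least 51.2-fold higher against a floor of 3 counts over the CT group; its reads may be shared with similar segments. Lower in IM were the ribosomal protein genes Rps14 (1937 ± 235 CPM in CT, 957 ± 228 in IM) and Rpl39 (303 ± 10.3 and 146 ± 38.4) and the G protein subunit gene Gng10 (25.2 ± 6.65 and 12.9 ± 0.720). Tmem174 measured 3.41 ± 0.479 and 0.691 ± 0.232 CPM, Vsig8 4.28 ± 0.409 and 1.44 ± 0.326, and the microRNA gene Mir703 11.9 ± 0.834 and 3.46 ± 1.91. For each of these 12 genes all 3 IM libraries lay on one side of all 3 CT libraries.

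**Figure D2:**
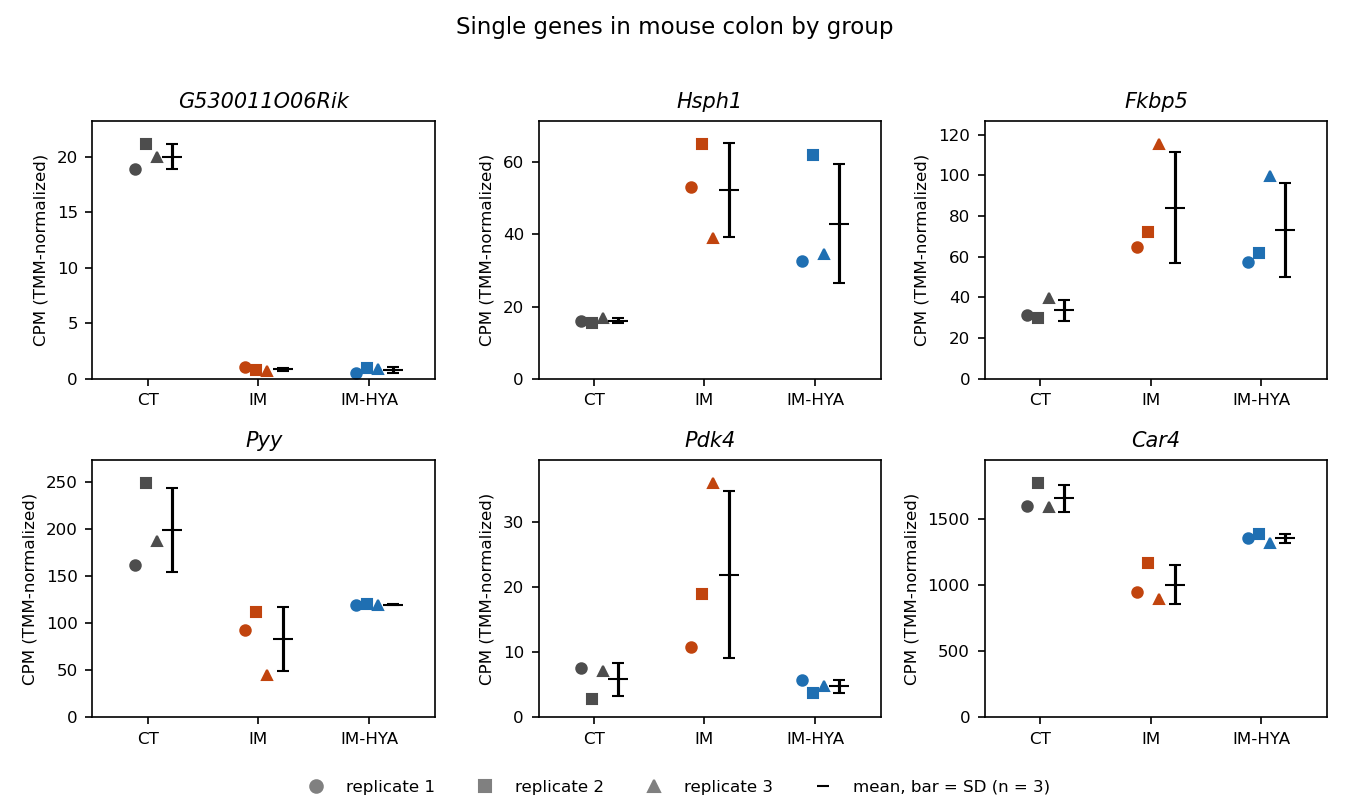
CPM (vertical axes, starting at 0) of 6 genes in the 3 groups (horizontal axes), with 1 point per library and the group mean ± SD (n = 3). G530011O06Rik falls from a mean of 19.98 CPM in CT to 0.829 in IM and 0.769 in IM-HYA, and Pdk4 means are 5.84, 21.9 and 4.78; of these genes only G530011O06Rik passed the test.

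Gene lists fixed in advance were compared between IM and CT with camera. Of 51 lists 14 rose and 2 fell, and 0 passed with an estimated correlation (smallest adjusted p = 0.489) or by fry (smallest adjusted p = 0.194). The number of lists passing was 10 without CT 3 and 8 without IM 1, and 2 of the 16 lists passed in every run that left out 1 library. Without CT 2 and IM 3 together the interferon, clock, nuclear oxidative phosphorylation, B cell, endothelial, mesothelium, erythrocyte and pancreatic calls also ended. On voom values the B cell, mesothelium, erythrocyte and pancreatic calls ended. Over all genes, edgeR passed 0 of the 928 list members, 124 had an unadjusted p under 0.05, and DESeq2 passed 22.

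Fat cell and lipid genes rose on average in IM, while IM 2 stayed close to CT. For adipocyte markers IM 2 had a mean log2 CPM of 3.39, against 2.79, 3.36 and 2.37 in the CT libraries. For the fatty acid synthesis list it had 4.67, against 4.72, 4.79 and 4.45. Adipocyte markers rose with a median log2 fold change of 2.62, and 16 of 17 members were fitted above 0 (camera adjusted p = 3.82e-13; adjusted p = 0.489 with an estimated correlation). Plin1, which coats fat droplets, measured 1.38 ± 0.185 CPM in CT and 13.5 ± 11.6 in IM, Plin4 11.8 ± 3.29 and 47.7 ± 41.3, and the droplet protein gene Cidea 0.383 ± 0.239 and 3.27 ± 2.43. Adjusted over the list alone, edgeR passed 13 members, 1 without CT 1, 0 without CT 3 and 4 without IM 3. Without IM 3, the library highest in these markers, the median was 1.04, and left-out runs gave camera adjusted p from 5.74e-24 to 1.15e-06. Fatty acid synthesis genes and targets of the sterol receptor LXR rose as a list (median 0.53, 18 of 26 above 0, camera adjusted p = 0.00211; adjusted p = 0.628 with an estimated correlation). The desaturase gene Scd1 measured 53.2 ± 7.73 CPM in CT and 1174 ± 1751 in IM, the lipogenic gene Thrsp 3.24 ± 1.70 and 97.8 ± 137, and Dgat2, which completes triglycerides, 17.3 ± 5.21 and 44.9 ± 18.8. Adjusted over the list alone, edgeR passed 7 of its members, 0 without any 1 of the CT libraries, 12 without IM 1 and 2 without IM 3. Without IM 1 the call ended (adjusted p = 0.078, left-out range 8.04e-07 to 0.078), and without IM 3 the median was 0.06. With the colon position covariate the median was 0.29 and 2 members passed over the list alone, and the adipocyte count was then 0.

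Fatty acid oxidation genes and PPAR targets rose by a median of 0.25, with 21 of 30 above 0 (camera adjusted p = 0.0194; adjusted p = 0.489 with an estimated correlation). Pdk4, which spares glucose by restraining pyruvate dehydrogenase, measured 5.84 ± 2.58 CPM in CT and 21.9 ± 12.9 in IM, and the lipid-sensing receptor gene Ppara 9.50 ± 3.19 and 39.8 ± 34.5. edgeR passed 0 members adjusted over the list alone (2 at an unadjusted p under 0.05, and 2 by DESeq2 over the list alone), and the call ended without IM 1 (adjusted p = 0.0727, left-out range 0.00485 to 0.0727), with 2 members then passing over the list alone, and the median was 0.12 with the 18S share covariate. Xenobiotic metabolism genes rose by a median of 0.43, with 24 of 35 above 0 (camera adjusted p = 0.00578; adjusted p = 0.489 with an estimated correlation). The retinaldehyde dehydrogenase gene Aldh1a1 measured 60.6 ± 13 and 285 ± 196 CPM and the glutathione transferase gene Gsta1 5.91 ± 1.97 and 11.8 ± 3.74, while Cyp2d34 measured 172 ± 8.25 and 102 ± 29.6. Of these members 0 passed over the list alone by edgeR, 10 had an unadjusted p under 0.05 and DESeq2 passed 8. Without IM 1 the xenobiotic call ended with a median of 0.13 (adjusted p = 0.229, left-out range 8.05e-06 to 0.229), and edgeR then passed 7 members over the list alone, and 1 without CT 3. The xenobiotic median was 0.24 with the 18S share covariate, and edgeR passed 7 members with it and 6 with the colon position covariate.

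Lymphocyte genes rose on average in IM, but not in IM 2. For T cell and NK cell markers IM 2 had a mean log2 CPM of −0.80, against −0.73, −0.80 and −0.40 in the CT libraries. T cell and NK cell markers had a median log2 fold change of 2.70, with 21 of 22 above 0 (camera adjusted p = 7.89e-10; adjusted p = 0.628 with an estimated correlation). The T cell receptor component gene Cd3e measured 0.441 ± 0.165 CPM in CT and 6.25 ± 8.06 in IM, the co-receptor gene Cd8a 0.182 ± 0.158 and 6.67 ± 9.37, and the kinase gene Lck 2.87 ± 0.305 and 18.1 ± 23.3. Adjusted over the list alone edgeR passed 3 members, 0 without any 1 of the CT libraries, IM 3, IM-HYA 2 or IM-HYA 3, 9 without IM 1 and 20 without IM 2. Without IM 3 the median was 0.65, and left-out runs gave adjusted p from 1.27e-20 to 0.00381. With the colon position covariate 0 T cell members passed over the list alone, and with the 18S share covariate 8. B cell markers rose by a median of 1.92, with 18 of 18 above 0 (camera adjusted p = 0.0106; adjusted p = 0.817 with an estimated correlation). The heavy chain gene Ighm measured 19.6 ± 3.64 and 108 ± 87.3 CPM and the receptor gene Cd79a 17.6 ± 2.96 and 96.0 ± 140. Over the B cell list alone edgeR passed 0 members (3 at an unadjusted p under 0.05, and 1 by DESeq2), and 18 without IM 2. The B cell call ended without CT 3 (0.0539), IM 1 (0.229) and IM 3 (0.239, median 0.37, tested lower), left-out adjusted p being 8.55e-22 to 0.239, and IM 2 lay below every CT library in these markers (mean log2 CPM −1.42).

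Antigen presentation genes rose by a median of 0.54, with 19 of 19 above 0 (camera adjusted p = 0.0106; adjusted p = 0.817 with an estimated correlation). The class I and II regulators Nlrc5 and Ciita measured 0.898 ± 0.543 and 3.94 ± 0.599 CPM in CT and 5.0 ± 5.84 and 13.9 ± 14.7 in IM. The direction turned without IM 3, where the list fell (median −0.32, camera adjusted p = 0.0158), and the median was 0.87 without IM 1. Their call ended without CT 3 (adjusted p = 0.053, left-out range 1.24e-06 to 0.053), and with the colon position covariate the median was 0.21 (adjusted p = 0.1). Interferon response genes rose by a median of 0.33, with 26 of 32 above 0 (camera adjusted p = 0.0106; adjusted p = 0.489 with an estimated correlation). Irf7, a regulator of interferon production, measured 29.7 ± 1.52 and 50.0 ± 15.9 CPM and Stat2, which relays the interferon signal, 11.1 ± 1.95 and 16.5 ± 2.21. That call ended without IM 2 (adjusted p = 0.0814, left-out range 0.00944 to 0.0814). Over each list alone edgeR passed 0 members, with 2 antigen presentation and 4 interferon genes at an unadjusted p under 0.05 and 0 by DESeq2 over either list; 3 antigen presentation genes passed edgeR without IM 2 and 2 interferon genes without IM 1.

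Stress, clock and mitochondrial lists passed as well. Heat shock genes rose by a median of 0.31, with 13 of 18 above 0 (camera adjusted p = 0.0106; adjusted p = 0.706 with an estimated correlation), and Hsph1 passed adjusted over the list alone (edgeR adjusted p = 0.00311), where 2 members passed without IM 1 and 4 without IM 3. Hsp90aa1 measured 176 ± 29.5 CPM in CT and 237 ± 28.2 in IM. The heat shock call ended without CT 2 (0.0869), CT 3 (0.0532), IM 1 (0.165) and IM 2 (0.341), in a left-out range of 3.46e-09 to 0.341. Circadian clock genes rose by a median of 0.47, with 14 of 20 above 0 (camera adjusted p = 0.0106; adjusted p = 0.706 with an estimated correlation). The clock output genes Hlf and Tef measured 8.87 ± 3.60 and 88.0 ± 19.4 CPM in CT and 17.0 ± 2.98 and 142 ± 33.4 in IM, while Npas2, of the activating arm, measured 16.2 ± 6.69 and 8.6 ± 1.53. Of the clock members 0 passed edgeR over the list alone, 7 had an unadjusted p under 0.05 and DESeq2 passed 0; without CT 1 edgeR passed 6. This call ended without CT 2 (0.102), CT 3 (0.094) and IM 1 (0.254), left-out adjusted p being 0.000133 to 0.254.

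Mitochondrially encoded transcripts rose by a median of 0.43, with 11 of 13 above 0 (camera adjusted p = 0.0124; adjusted p = 0.817 with an estimated correlation). The complex I genes ND5 and ND4L measured 568 ± 109 and 26.3 ± 12.2 CPM in CT and 1003 ± 270 and 100.3 ± 74.6 in IM, and ND4L alone passed over the list alone (edgeR adjusted p = 0.049), with 3 members passing without IM 2 and 0 without CT 1, CT 2, CT 3, IM 1 or any 1 of the IM-HYA libraries. The median was 0.81 without CT 2, 0.21 without CT 3, 0.70 without IM 2 and 0.67 without IM 3. The mitochondrial call ended without CT 1 (0.102), CT 3 (0.162) and IM 1 (0.502, median −0.19), in a left-out range of 6.69e-06 to 0.502, and with the 18S share covariate (0.113, median 0.07). Nuclear genes of oxidative phosphorylation fell as a list with a median of −0.18, with 27 of 34 below 0 (camera adjusted p = 0.0106; adjusted p = 0.817 with an estimated correlation). Cox7a2 of complex IV measured 267 ± 5.24 and 184 ± 81.5 CPM and Ndufb8 of complex I 308 ± 8.39 and 234 ± 58.0. edgeR passed 0 of its members over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Its call ended without CT 2 (0.0533), IM 1 (0.229) and IM 3 (0.373, median −0.07), left-out adjusted p being 3.07e-06 to 0.373, and the median was −0.39 without IM 2 and −0.29 with the colon position covariate.

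Markers of tissue outside the epithelium also rose. Endothelial markers had a median of 0.54, with 14 of 17 above 0 (camera adjusted p = 0.0124; adjusted p = 0.817 with an estimated correlation), and the lymphatic receptor gene Flt4 measured 10.6 ± 1.13 CPM in CT and 22.3 ± 15.6 in IM. The endothelial call ended without CT 3 (0.094), IM 1 (0.078) and IM 3 (0.969, median 0.01, tested lower), left-out adjusted p being 6.45e-05 to 0.969. Mesothelium markers had a median of 1.12, with 8 of 10 above 0 (camera adjusted p = 0.0149; adjusted p = 0.628 with an estimated correlation), and Msln measured 0.645 ± 0.259 and 1.78 ± 1.40 CPM. That call ended without CT 2 (0.0949), CT 3 (0.0695), IM 1 (0.143) and IM 3 (0.177, median 0.69), in a left-out range of 0.00107 to 0.177, and with the CPM filter (0.146). Erythrocyte markers had a median of 0.73, with 7 of 8 above 0 (camera adjusted p = 0.0269; adjusted p = 0.628 with an estimated correlation), and Alas2, of haem synthesis, measured 0.652 ± 0.637 and 3.73 ± 2.92 CPM. The erythrocyte call ended without CT 2 (0.102), CT 3 (0.162), IM 1 (0.231) and IM 3 (0.159, median 0.37), in a left-out range of 0.00237 to 0.231, with medians of 1.33 without CT 1, 1.16 without IM 2 and 1.18 with the colon position covariate, and with the 18S share covariate (0.137). Pancreatic acinar markers fell with a median of −7.19, with 21 of 21 below 0 (camera adjusted p = 0.0106; adjusted p = 0.817 with an estimated correlation). That fall rested on CT 2: without CT 2 the list rose, with a median of 5.13 (camera adjusted p = 1.68e-05). Without CT 2 and IM 3 together the median was 1.83 (adjusted p = 0.14), and the call ended without IM 1 (0.231) and IM 2 (0.19), left-out adjusted p being 1.93e-11 to 0.231, and with the colon position covariate (0.156) and the 18S share covariate (0.22). Over these 4 lists alone edgeR passed 0 members, with 1 endothelial, 2 mesothelial, 3 erythrocyte and 2 pancreatic genes at an unadjusted p under 0.05 and 0, 0, 1 and 1 by DESeq2. Without IM 2 edgeR passed 2 erythrocyte genes and without CT 3 it passed 1 pancreatic gene.

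**Figure D3:**
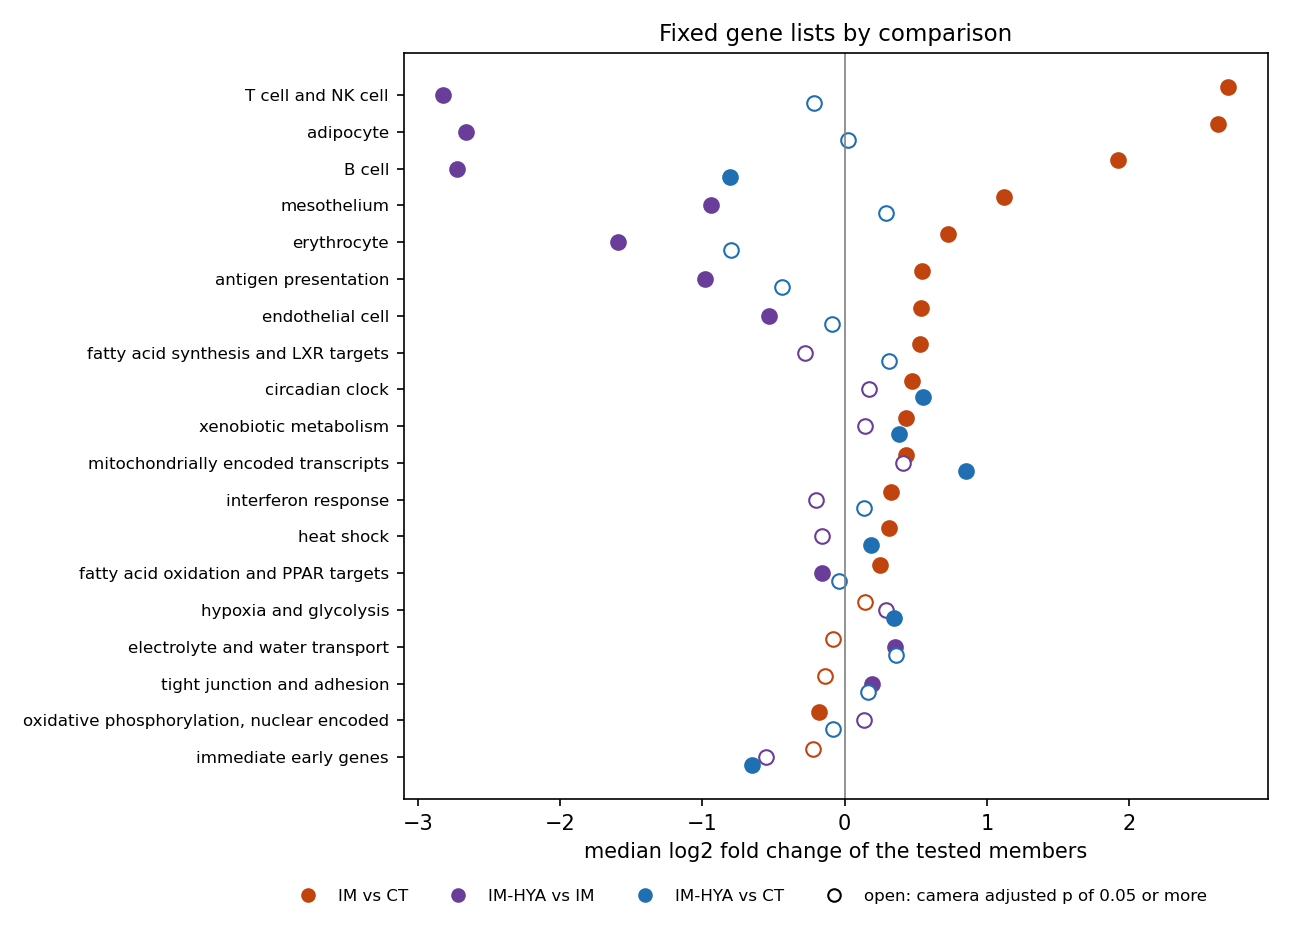
Median log2 fold change (horizontal axis) of 19 gene lists (vertical axis) in the 3 comparisons, shown by colour; filled points passed camera at an adjusted p under 0.05 and open points did not. The adipocyte and T cell lists sit at 2.62 and 2.70 in IM against CT and at −2.66 and −2.83 in IM-HYA against IM; the pancreatic acinar list is not drawn.

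Several groups of interest did not pass in IM against CT. In the glucocorticoid response list (camera adjusted p = 0.139, median 0.20), Fkbp5, a feedback regulator of the glucocorticoid receptor, measured 33.5 ± 5.19 CPM in CT and 84.2 ± 27.3 in IM, log2 fold change 1.33 (SE 0.29). Over that list alone edgeR passed Fkbp5 (adjusted p = 0.0304) and Pdk4 (adjusted p = 0.0378), with 3 passing without IM 1, 1 without IM 2 or any 1 of the IM-HYA libraries, and 0 without IM 3 or any 1 of the CT libraries. The glucocorticoid list passed without IM 3 (camera adjusted p = 0.0473) and with the colon position covariate (camera adjusted p = 0.0189); its median was 0.36 without CT 1, 0.33 without CT 2, −0.03 without IM 1 and 0.12 with the 18S share covariate. Among enteroendocrine genes (camera adjusted p = 0.295, tested lower, median −0.21, mean 0.17), the gut hormone genes Pyy and Nts passed over the list alone in opposite directions (edgeR adjusted p = 0.0279 and 0.0255). Nts, the neurotensin gene, measured 0.104 ± 0.0914 CPM in CT and 17.4 ± 18.6 in IM, with the IM libraries at 0.180, 14.9 and 37.1. Pyy, the gene of the satiety hormone peptide YY, measured 199 ± 44.5 CPM in CT and 83.1 ± 34.2 in IM. That count of 2 was 0 without any 1 of the CT libraries, 3 without IM 1, and 1 without IM 3 or any 1 of the IM-HYA libraries, and 0 with the colon position covariate, where the median was −0.34. The colonocyte carbonic anhydrase gene Car4 measured 1658 ± 101 and 1006 ± 146 CPM (log2 fold change −0.72, SE 0.21, edgeR adjusted p = 0.621). The proximal colon list did not pass (camera adjusted p = 0.243, median 0.07), with Hoxb6 at 1.33 ± 1.05 and 39.2 ± 46.7 CPM and Osr2 at 0.579 ± 0.255 and 14.2 ± 16.1.

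Receptors and transporters for fatty acids and metabolites had a median of 0.67 in IM against CT (camera adjusted p = 0.182). edgeR passed 0 of 18 members over the list alone, 3 had an unadjusted p under 0.05, and DESeq2 passed 1. The long-chain fatty acid receptor gene Ffar4 measured 22.3 ± 6.05 CPM in CT, 43.4 ± 27.9 in IM and 22.7 ± 11.5 in IM-HYA, and the short-chain receptor gene Ffar2 24.6 ± 28.9, 45.5 ± 37.3 and 15.8 ± 22.5. Ffar4 was higher where Hoxd13 was low, at 29.2 CPM in CT 3, 50.9 in IM 2, 66.7 in IM 3 and 36.0 in IM-HYA 2. It measured 12.6 to 19.5 CPM in the other libraries, with IM 1 lowest. The bile acid transporter gene Slc10a2 measured 3.98 ± 2.0, 31.5 ± 33.0 and 9.39 ± 3.13 CPM, and the bile acid receptor gene Nr1h4 21.7 ± 2.1, 29.2 ± 4.03 and 30.0 ± 1.95. Hormone and muscle-acting factor genes had a median of 0.27 while the test pointed lower (camera adjusted p = 0.989). Of 21 members 0 passed edgeR over the list alone, 7 had an unadjusted p under 0.05 and DESeq2 passed 3. Among them Gcg, the proglucagon gene, measured 85.5 ± 88.4, 23.7 ± 15 and 40.1 ± 30.1 CPM in CT, IM and IM-HYA, Gdf15 9.29 ± 2.65, 5.01 ± 1.03 and 8.04 ± 3.32, and Igfbp3 73.0 ± 6.99, 51.9 ± 12.2 and 61.7 ± 7.37. Tight junction genes had a median of −0.14 (camera adjusted p = 0.202), and without IM 1 this list passed (median −0.34, adjusted p = 0.0255, left-out range 0.0255 to 0.427), while without IM 3 the median was 0.11.

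The comparison of IM-HYA with IM asked whether the HYA diet changed the colon of immobilized mice. No gene passed. With edgeR 0 of 18414 genes were called, 234 were higher and 1177 lower at an unadjusted p under 0.05 (7.66%), and DESeq2 called 43, 6 higher and 37 lower. Groups did not overlap for 992 genes higher and 795 lower in IM-HYA, 9.70% of genes, where chance gives 10%. Without IM 1, which differed from the other IM libraries in colon position (Hoxd13 99.5 CPM), edgeR called 871 genes, 306 higher and 565 lower, and without IM 2 it called 1. The count at an unadjusted p under 0.05 was 5999 without IM 1, 303 without IM 3, 535 without IM-HYA 1 and 512 without IM-HYA 3.

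The genes with the smallest p in IM-HYA against IM, none passing (edgeR adjusted p = 0.604 for each), included Pdk4 at 21.9 ± 12.9 CPM in IM and 4.78 ± 0.999 in IM-HYA, log2 fold change −2.20 (SE 0.48). Cyp4b1 measured 14.0 ± 10.9 and 2.76 ± 1.18 CPM, the microtubule protein gene Camsap1 23.5 ± 4.13 and 13.5 ± 1.15, and the T cell genes Cd3d and Cd5 8.33 ± 12.0 and 3.10 ± 4.21 in IM and 0.409 ± 0.181 and 0.152 ± 0.0623 in IM-HYA. On the higher side, the arrestin-domain gene Arrdc3 measured 37.2 ± 6.05 and 78.5 ± 23.5 CPM, log2 fold change 1.08 (SE 0.24). The histone methyltransferase gene Setdb2 had no read in CT or IM and 239 counts in IM-HYA (1.65 ± 0.769 CPM), at least 55.2-fold higher than in IM against a floor of 3 counts over the group. The other 5 were immunoglobulin segments, whose reads may be shared: Igkv6-13, Ighv1-5, Ighv1-39 and Ighv6-6 had means of 6.18, 1.93, 10.3 and 2.56 CPM in IM-HYA, and Igkv3-4 of 14.5 CPM in IM and 0.174 in IM-HYA. In each of these 12 genes the IM-HYA libraries lay on one side of the IM libraries.

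Of 51 lists, camera called 9 lower and 2 higher in IM-HYA than in IM, and 0 passed with an estimated correlation (smallest adjusted p = 0.683) or by fry (smallest adjusted p = 0.597). The number passing was 18 without IM 2, and 2 of the 11 passed in every run that left out 1 library. Without CT 2 and IM 3 together the B cell, antigen presentation, endothelial, mesothelium, tight junction and electrolyte calls also ended, and on voom values the pancreatic and electrolyte calls ended. Over all genes edgeR passed 0 of 928 list members, 133 had an unadjusted p under 0.05, and DESeq2 passed 16.

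Adipocyte and lymphocyte markers fell on average in IM-HYA against IM. IM 2 was itself low in adipocyte markers, at a mean log2 CPM of 3.39 against 2.43, 3.47 and 2.64 in the IM-HYA libraries. The adipocyte list had a median of −2.66, with 15 of 17 below 0 (camera adjusted p = 6.48e-12; adjusted p = 0.683 with an estimated correlation). Cfd, the adipsin gene, measured 759 ± 910 CPM in IM and 64.9 ± 41.3 in IM-HYA, and the droplet protein gene Cidec 139 ± 178 and 8.66 ± 6.26. Over the list alone edgeR passed 13 members, and 0 without IM 3, where the median was −1.32; left-out adjusted p ran from 9.04e-26 to 0.000308. With the colon position covariate 6 adipocyte members passed over the list alone, and with the 18S share covariate 0; over the T cell and B cell lists 0 did with either. The T cell and NK cell list had a median of −2.83, with 22 of 22 below 0 (camera adjusted p = 3.64e-11; adjusted p = 0.842 with an estimated correlation). Cd3e measured 6.25 ± 8.06 and 0.618 ± 0.121 CPM and Trbc2 8.17 ± 10.5 and 0.843 ± 0.192. Of its members edgeR passed 15 over the list alone, 8 without CT 3 and 0 without IM 3 or any 1 of the IM-HYA libraries, and the median was −1.02 without IM 3 (left-out adjusted p 9.04e-26 to 0.00011). B cell markers fell with a median of −2.73, with 18 of 18 below 0 (camera adjusted p = 7.27e-06; adjusted p = 0.842 with an estimated correlation), Cd79a measuring 96.0 ± 140 and 7.95 ± 1.99 CPM. Over the B cell list alone edgeR passed 7 members, 1 without IM 1, 18 without IM 2 and 0 without IM 3, any 1 of the CT libraries or any 1 of the IM-HYA libraries. Without IM 3 the B cell median was −1.09, and the call ended without IM 1 (adjusted p = 0.0673, left-out range 1.02e-37 to 0.0673).

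Antigen presentation genes fell with a median of −0.98, with 17 of 19 below 0 (camera adjusted p = 3.58e-05; adjusted p = 0.842 with an estimated correlation). The class II gene H2-Ab1 measured 386 ± 398 CPM in IM and 131 ± 5.97 in IM-HYA and the invariant chain gene Cd74 815 ± 731 and 331 ± 55.4. The call ended without IM 3 (adjusted p = 0.395, median −0.13, left-out range 7.67e-12 to 0.395). Over that list alone edgeR passed 0 members (11 at an unadjusted p under 0.05, and 0 by DESeq2), 11 without IM 1 and 13 without IM 2. Their median was −0.50 with the colon position covariate and −0.54 with the 18S share covariate, where the endothelial medians were −0.33 and −0.34. Erythrocyte markers fell with a median of −1.59, with 6 of 8 below 0 (camera adjusted p = 0.00183; adjusted p = 0.683 with an estimated correlation). Their call ended without IM 1 (adjusted p = 0.144, left-out range 2.66e-07 to 0.144), and edgeR passed 2 over the list alone, 6 without CT 3, 5 without IM 2 and 0 without IM-HYA 1 or IM-HYA 2 or with either covariate. Endothelial markers fell with a median of −0.54, with 15 of 17 below 0 (camera adjusted p = 0.0049; adjusted p = 0.842 with an estimated correlation), with Flt4 at 22.3 ± 15.6 and 10.4 ± 1.61 CPM. The endothelial call ended without IM 1 (0.116) and IM 3 (0.212, median −0.15), left-out adjusted p being 4.3e-06 to 0.212. Mesothelium markers fell with a median of −0.94, with 8 of 10 below 0 (camera adjusted p = 0.0489; adjusted p = 0.842 with an estimated correlation). Their call ended without IM 1 (0.3) and IM 3 (0.12, median −0.28), in a left-out range of 0.0106 to 0.3 with a median of −1.62 without IM-HYA 2, and under RLE (0.0518), upper quartile scaling (0.0505) and the CPM filter (0.173). The pancreatic acinar list also fell (camera adjusted p = 1.74e-05; adjusted p = 0.842 with an estimated correlation), at a mean log2 CPM of 4.21, −0.66 and 7.48 in the IM libraries and −1.08, −1.70 and 0.83 in the IM-HYA libraries. Its call ended without IM 1 (adjusted p = 0.0673, left-out range 6.87e-11 to 0.0673), and edgeR passed 0 members over that list alone and 17 without CT 2. In the endothelial, mesothelium and pancreatic lists 4, 1 and 0 members had an unadjusted p under 0.05, edgeR passed 0 over each list alone, and DESeq2 passed 0, 1 and 0. edgeR passed 5 endothelial genes without IM 1 and 6 without IM 2, and 1 mesothelium gene without CT 2.

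Fatty acid oxidation genes and PPAR targets fell in IM-HYA against IM with a median of −0.16, with 18 of 30 below 0 (camera adjusted p = 0.0382; adjusted p = 0.683 with an estimated correlation). Pdk4 passed over the list alone (edgeR adjusted p = 0.0352), and Ppara measured 39.8 ± 34.5 and 12.3 ± 4.08 CPM. Without IM 1 the call ended (adjusted p = 0.143, left-out range 0.000407 to 0.143) and 8 members passed over the list alone; 0 did without CT 1, CT 3, IM 2, IM 3 or any 1 of the IM-HYA libraries, and the median was −0.31 without IM-HYA 3 and −0.10 with the 18S share covariate.

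Tight junction and adhesion genes rose by a median of 0.19, with 22 of 28 above 0 (camera adjusted p = 0.0465; adjusted p = 0.842 with an estimated correlation). Marveld3 measured 26.8 ± 20.5 CPM in IM and 53.5 ± 9.35 in IM-HYA, occludin (Ocln) 54.4 ± 37.3 and 90.7 ± 27.7, and claudin 8 (Cldn8) 13.9 ± 16.5 and 36.3 ± 20.7, while claudin 5 (Cldn5), an endothelial claudin, measured 27.3 ± 28.5 and 9.52 ± 0.124. IM 3 was the lowest library for this list (mean log2 CPM 5.48), and the call ended without IM 3 (0.979, median 0.01) and IM-HYA 3 (0.0611), in a left-out range of 0.0155 to 0.979. It also ended with the colon position covariate (0.246, median 0.09), the 18S share covariate (0.313) and the CPM filter (0.0574). Electrolyte and water transport genes rose by a median of 0.35, with 18 of 28 above 0 (camera adjusted p = 0.0465; adjusted p = 0.842 with an estimated correlation). Car4 measured 1006 ± 146 and 1355 ± 30.9 CPM and Hsd11b2, which protects the mineralocorticoid receptor, 174 ± 104 and 307 ± 32.2, while the potassium channel gene Kcnn4 measured 82.8 ± 30.7 and 49.6 ± 6.0. The electrolyte call ended without IM 3 (0.373, median 0.11) and IM-HYA 3 (0.0611), left-out adjusted p being 0.0214 to 0.373, and with the CPM filter (0.0574). Over the tight junction and electrolyte lists alone edgeR passed 0 members, with 1 in each at an unadjusted p under 0.05 and 0 by DESeq2; without IM 1 it passed 6 and 10, with medians of 0.45 and 0.61.

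Hormone genes did not pass in IM-HYA against IM (camera adjusted p = 0.382). edgeR passed 0 of 21 over the list alone, 7 had an unadjusted p under 0.05, and DESeq2 passed 1. Pyy measured 83.1 ± 34.2 CPM in IM and 119 ± 0.690 in IM-HYA (log2 fold change 0.52, SE 0.31), Igf1 23.3 ± 14.3 and 11.1 ± 1.41 (−1.07, SE 0.42), the secretin gene Sct 43.6 ± 46.5 and 4.84 ± 3.41 (−3.17, SE 1.06) and the muscle-acting cytokine gene Il15 6.21 ± 1.69 and 10.7 ± 3.57 (0.78, SE 0.34). The receptor and transporter list did not pass (camera adjusted p = 0.191), with Ffar4 at a log2 fold change of −0.93 (SE 0.54) and the monocarboxylate transporter gene Slc5a8 at 97.9 ± 86.8 and 194 ± 55.4 CPM. Nts alone passed over the enteroendocrine list alone (edgeR adjusted p = 0.0351), at 17.4 ± 18.6 and 0.189 ± 0.136 CPM. Over that list 3 genes passed without IM 1, and 0 without CT 3, IM 2, IM 3 or any 1 of the IM-HYA libraries. The list did not pass (camera adjusted p = 0.911). Nts measured 0.180, 14.9 and 37.1 CPM in the IM libraries. It was thus high only in IM 2 and IM 3, where Hoxb6 was also high (23.5 and 91.7 CPM).

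The comparison of IM-HYA with CT asked whether immobilized mice on the HYA diet still differed from controls; cast and diet changed together here. G530011O06Rik fell by 4.69 on the log2 scale (SE 0.33, edgeR adjusted p = 0.00194), with all 3 IM-HYA libraries below all 3 CT libraries. Over 24 alternatives its adjusted p ran from 2.28e-43 to 0.184, and unfiltered log2(FPKM + 1) values ended the call (adjusted p = 0.184). edgeR called no other of the 18414 genes, with 425 higher and 532 lower at an unadjusted p under 0.05 (5.20%), and DESeq2 called 15, 10 higher and 5 lower. Groups did not overlap for 1987 genes higher and 2089 lower, 22.1% of genes, where chance gives 10%. Genes are not independent, so 10% is no bound where libraries differ as a whole. The Rn18s-rs5 share also parted these groups, at 5.42%, 8.76% and 23.2% in CT and 4.19%, 4.60% and 3.66% in IM-HYA. edgeR called 2 genes without CT 1. The count at an unadjusted p under 0.05 was 2079 without IM 1, 1714 without IM 3, 362 without IM-HYA 1, 493 without IM-HYA 2 and 536 without IM-HYA 3.

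The genes with the smallest p in IM-HYA against CT, none passing, had edgeR adjusted p of 0.721 (Ighv6-6) or 0.854. Hsph1 measured 16.1 ± 0.766 CPM in CT and 43 ± 16.5 in IM-HYA (log2 fold change 1.42, SE 0.28), Fbrs 22.9 ± 1.82 and 42.7 ± 3.20, and Xlr3a 0.642 ± 0.291 and 3.80 ± 0.489. Setdb2 was at least 42-fold higher than in CT, where it had no read. The segments Ighv6-6 and Igkv6-13 measured 2.56 ± 1.49 and 6.18 ± 5.26 CPM in IM-HYA and 0.0993 and 0.019 in CT. Lower in IM-HYA were Plau, the urokinase gene (33.2 ± 10.6 and 15.7 ± 1.67 CPM), the calcium-binding protein gene S100a16 (613 ± 91.3 and 292 ± 33.2), Bok, a BCL2 family member (33.6 ± 2.05 and 19.0 ± 2.14), and the matrix protease gene Adamts4 (2.57 ± 0.699 and 0.716 ± 0.246). Mir703 measured 11.9 ± 0.834 and 4.09 ± 0.712 CPM and the small nucleolar RNA gene Rnu3b3 1.05 and 0.0413. All 3 IM-HYA libraries lay on one side of the CT libraries for each of these 12 genes.

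Clock genes had the smallest p of the lists that rose in IM-HYA against CT. Their median log2 fold change was 0.55, with 14 of 20 above 0 (camera adjusted p = 1.96e-07; adjusted p = 0.824 with an estimated correlation). Per2 and Per3, of the repressing arm of the clock, measured 12.6 ± 5.15 and 16.9 ± 5.74 CPM in CT, 24.0 ± 10.1 and 26.0 ± 7.46 in IM and 37.4 ± 9.42 and 38.6 ± 6.27 in IM-HYA, with log2 fold changes against CT of 1.57 (SE 0.37) and 1.19 (SE 0.29). The output gene Hlf measured 8.87 ± 3.60, 17.0 ± 2.98 and 19.5 ± 3.52 CPM. Over the list alone edgeR passed 6 members, all higher (Per2 and Per3 at an adjusted p of 0.0223), and 0 without CT 2, CT 3 or IM-HYA 1 or with the 18S share covariate, and 3 without IM-HYA 3. Left-out runs gave camera adjusted p from 1.28e-09 to 0.000157. The list did not pass in IM-HYA against IM (camera adjusted p = 0.094).

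**Figure D4:**
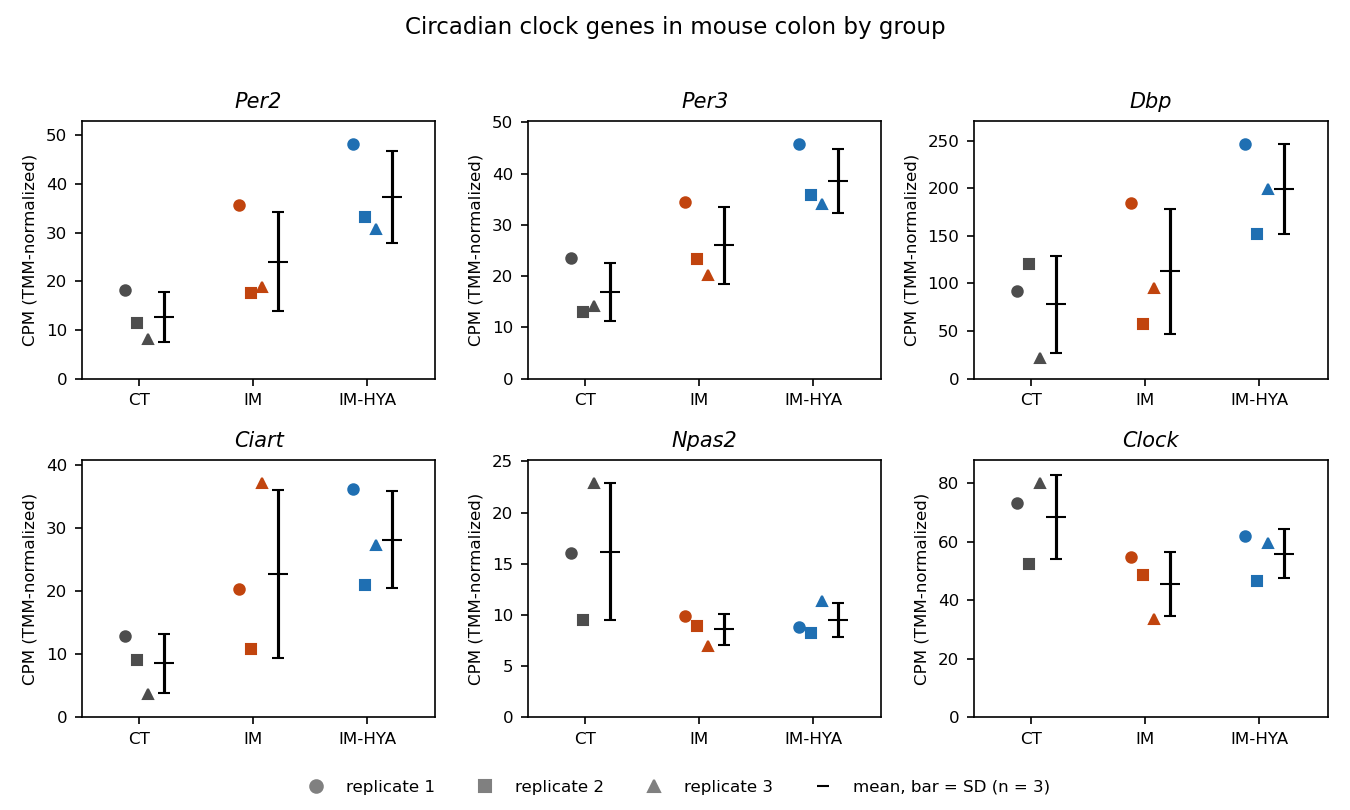
CPM (vertical axes, starting at 0) of 6 clock genes in the 3 groups (horizontal axes), with 1 point per library and the group mean ± SD (n = 3). Per2 means run from 12.6 in CT to 24.0 in IM and 37.4 in IM-HYA, while Npas2 means are 16.2, 8.6 and 9.48; none passed over all genes.

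Immediate early genes fell in IM-HYA against CT with a median of −0.65, with 19 of 23 below 0 (camera adjusted p = 2.42e-05; adjusted p = 0.892 with an estimated correlation). Egr1, a transcription factor induced by many stimuli, measured 47.1 ± 35.6 CPM in CT and 12.0 ± 6.70 in IM-HYA, the orphan receptor gene Nr4a1 32.9 ± 34.1 and 7.61 ± 2.70, and Ccn1 47.8 ± 47.5 and 10.5 ± 3.52. The call ended without CT 1 (adjusted p = 0.128, median −0.17, left-out range 1.41e-09 to 0.128). Xenobiotic metabolism genes rose by a median of 0.38, with 30 of 35 above 0 (camera adjusted p = 2.65e-05; adjusted p = 0.325 with an estimated correlation). Gclc, of glutathione synthesis, measured 18.3 ± 2.33 and 33.2 ± 5.24 CPM, the glucuronosyltransferase gene Ugt1a6a 3.55 ± 5.03 and 23.2 ± 6.34, and Gsta1 5.91 ± 1.97 and 10.2 ± 0.231. Left-out runs gave camera adjusted p from 1.08e-05 to 0.00067, and with the 18S share covariate the median was 0.18 (camera adjusted p = 0.00148). Over the 2 lists alone edgeR passed 0 members, with 7 immediate early and 6 xenobiotic genes at an unadjusted p under 0.05 and 5 and 0 by DESeq2. Without CT 2 edgeR passed 2 immediate early genes, and it passed 1 xenobiotic gene without CT 3 and 3 without IM 1.

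Mitochondrially encoded transcripts rose by a median of 0.85 in IM-HYA against CT, with 12 of 13 above 0 (camera adjusted p = 2.65e-05; adjusted p = 0.892 with an estimated correlation), ND4 measuring 646 ± 455 and 1636 ± 144 CPM. With the 18S share covariate the median was 0.14 and the call ended (adjusted p = 0.0753). Without CT 2 the median was 1.37 and edgeR passed 8 members over the list alone, and 3 without IM 1, against 0 with all libraries; left-out camera adjusted p ran from 1.57e-10 to 0.00788. Hypoxia and glycolysis genes rose by a median of 0.35, with 23 of 25 above 0 (camera adjusted p = 0.00464; adjusted p = 0.892 with an estimated correlation). The growth factor gene Vegfa measured 26.8 ± 2.28 and 40.8 ± 2.09 CPM and the glycolytic genes Hk1 and Eno1 87.6 ± 23.0 and 297 ± 117 in CT and 137 ± 9.61 and 435 ± 39.6 in IM-HYA. Their call ended without CT 3 (adjusted p = 0.197, median 0.21, left-out range 0.000585 to 0.197), the library highest in Rn18s-rs5, and with the 18S share covariate (adjusted p = 0.716, median −0.05); with the colon position covariate the median was 0.19. Heat shock genes rose by a median of 0.19, with 15 of 18 above 0 (camera adjusted p = 0.0342; adjusted p = 0.892 with an estimated correlation), and Hsph1 passed over the list alone (edgeR adjusted p = 0.0112), while without CT 1 or CT 2 no member did. The heat shock call ended without CT 2 (0.266), CT 3 (0.111), IM 1 (0.0804) and IM-HYA 2 (0.111), in a left-out range of 0.00422 to 0.266, and with the 18S share covariate (0.393, median 0.08) and protein-coding genes alone (0.051), as well as on voom values and without CT 2 and IM 3 together. Over the mitochondrial and hypoxia lists alone edgeR passed 0 members, with 3 and 1 at an unadjusted p under 0.05 and 0 and 1 by DESeq2.

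B cell markers fell in IM-HYA against CT with a median of −0.81, with 15 of 18 below 0 (camera adjusted p = 0.0234; adjusted p = 0.966 with an estimated correlation), Cd79b measuring 13.1 ± 2.22 and 4.52 ± 1.71 CPM. edgeR passed 0 over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. The call ended without CT 1 (0.0528), CT 2 (0.0625), IM 1 (0.112) and IM-HYA 2 (0.319, median −0.43), in a left-out range of 4.13e-05 to 0.319, and with the colon position covariate (0.0655), the 18S share covariate (0.125, median −0.41) and voom values. Pancreatic acinar markers fell (camera adjusted p = 1.85e-08; adjusted p = 0.892 with an estimated correlation), at a mean log2 CPM of −1.06, 14.72 and 2.38 in the CT libraries. Over that list alone edgeR passed 19 of 21, and 0 without CT 2, IM 1, IM 3 or any 1 of the IM-HYA libraries, or with either covariate or no filter; left-out camera adjusted p ran from 9.53e-24 to 0.0103, the last without CT 2. Adipocyte and T cell markers, which passed in both other comparisons, had medians of 0.02 and −0.22 (camera adjusted p = 0.933 and 0.598). Of 51 lists 5 rose and 3 fell, 4 passing in every run that left out 1 library, and 0 passed with an estimated correlation (smallest adjusted p = 0.325) or by fry (smallest adjusted p = 0.17). Over all genes edgeR passed 0 of 928 list members, 76 had an unadjusted p under 0.05, and DESeq2 passed 1. Hormone, tight junction and receptor genes did not pass (camera adjusted p = 0.331, 0.467 and 0.999), with Pyy at a log2 fold change of −0.74 (SE 0.31) and Fkbp5 at 1.12 (SE 0.29).

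The test across all 3 groups asked which genes differed anywhere. G530011O06Rik alone passed (edgeR adjusted p = 0.000628), while 1232 genes had an unadjusted p under 0.05 (6.69%) and DESeq2 called 90. Without IM 1 or without IM 2 edgeR called 2 genes. Whether genes moved by the cast moved back with HYA was read from the IM against CT and IM-HYA against IM fold changes, which share the IM libraries. No gene passed in both in opposite directions with edgeR. Across 18414 genes, which are not independent replicates, the fold changes correlated at r = −0.455. Data simulated without group effects gave a median of −0.497 (−0.541 to −0.437), and 100 relabellings of the libraries a median of −0.494 (−0.872 to 0.147). The covariance was −0.375, against a median of −0.227 simulated (−0.270 to −0.192) and −0.344 relabelled (−1.10 to 0.0923). It thus lay within the range of the relabellings. Part of any excess over the simulated value may come from the shared IM libraries, which were too few to split. Without IM 1 the correlation was −0.717 and without IM 3 it was −0.285; without CT 1 it was −0.297. G530011O06Rik passed in the same direction against CT in both cast groups, which share the CT libraries; data simulated without group effects gave at most 1 such gene (median 0). Its IM-HYA against IM log2 fold change was −0.11 (SE 0.29, edgeR adjusted p = 0.876).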

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

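The tests with CT 2 and IM 3 left out together and with a colon position or 18S share covariate were chosen only after the data were seen. edgeR called 1 gene in IM against CT, 0 in IM-HYA against IM, 1 in IM-HYA against CT and 1 across groups, and 16, 11 and 8 lists passed camera. DESeq2 called 65, 43, 15 and 90 genes. On counts simulated for IM against CT it made 60 false calls among 177, where edgeR made 2 among 84. Those counts were drawn with edgeR's dispersions. Log2(FPKM + 0.1) gave 2, 1, 3 and 4 genes. Log2(FPKM + 1) gave 1 in IM-HYA against IM, 7 in IM-HYA against CT and 2 across groups, and without a filter 0 in IM against CT, in IM-HYA against CT and across groups. limma-voom with quality weights called 1 gene in IM-HYA against IM. Protein-coding genes alone gave 0 in IM against CT, in IM-HYA against CT and across groups, since G530011O06Rik is then left out. Without CT 2 and IM 3 together the calls were 0 in IM against CT, 1 in IM-HYA against IM and 2 across groups, and 13 lists passed in IM-HYA against CT. In IM-HYA against IM 21 lists passed with the position covariate and 24 with the 18S covariate; with an estimated correlation 0 lists passed in each comparison. Leaving out 1 library gave 1 to 2, 0 to 871 (without IM 1), 1 to 2 and 1 to 2 genes, 8 to 21, 10 to 18 and 6 to 12 lists, and a correlation of −0.717 (without IM 1) to −0.285. Replicate numbers did not consistently pair the libraries. Same-numbered libraries deviated together at r = −0.273 to 0.364, over 0.1 in 5 of 9 pairs. Their median r was 0.210, against −0.0606 for differently numbered pairs, so a partial pairing is not excluded. Not every library correlated best with its own number. With a replicate block the calls were 1, 0, 1 and 1, with 14, 9 and 8 lists and a correlation of −0.508. For the remaining changes the cause was not tested. In IM against CT 2 lists passed in the other direction without 1 library: pancreatic markers without CT 2 (median 5.13, adjusted p = 1.68e-05) and antigen presentation without IM 3 (median −0.32, adjusted p = 0.0158). No named gene changed sign past its threshold: 14026 of 14128 values under alternatives stayed on their side of the threshold (486 that did not pass changed sign), 99 were past it only under the alternative and 3 only without it. The simulation recovered 47.8% of 4-fold and 0% of 2-fold changes in IM against CT with edgeR, so 2-fold changes would mostly be missed. A correlation over the genes called across groups was not possible with 1 gene.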

Other observations

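The tests of G530011O06Rik, of genes parting CT from the cast groups, of the clock and of attached tissue were chosen only after the result was seen. In all, 3 genes parted CT from all 6 cast libraries by 4-fold or more: G530011O06Rik, lower with the cast, and the immunoglobulin segments Ighv1-84 and Igkv3-10, higher with the cast. Of 84 choices of 3 libraries 10 gave as many genes, the highest other being 13 for IM 2, IM 3 and IM-HYA 2, so chance is not excluded for this count.

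The 3 against 3 comparisons have 10 splits of their libraries, too few for a share under 0.05. In IM against CT 2 splits called as many genes as the real 1 (highest other 1) and 4 passed as many lists (16, highest other 29). In IM-HYA against IM all 10 called as many genes as the real 0 and 7 passed as many lists (11, highest other 25). A split of these libraries called 648 genes, which points to a structure of the samples: it set IM 1, IM-HYA 1 and IM-HYA 3, high in Hoxd13, against IM 2, IM 3 and IM-HYA 2. In IM-HYA against CT 1 split called as many genes (1, highest other 0) and 9 passed as many lists (8, highest other 22). Across all groups 11 of 100 regroupings called as many genes (1, highest other 3), 4 of them with the CT libraries together, which keeps the difference of G530011O06Rik, and 7 with them apart, and 59 of 100 gave a correlation as negative (−0.455, lowest other −0.872), so chance is not excluded for either.

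G530011O06Rik was lower in both cast groups than in CT. Loss of the surrounding X chromosome segment was argued against. Within 1 Mb, the tested genes Arhgap6, Hccs and Mid1 had log2 fold changes of −0.14, −0.02 and 0.30 in IM-HYA against CT. In IM against CT their values were −0.77, −0.26 and −0.05. With Erdr1 added, which was not among the genes of that window, the medians of the 4 genes were 0.14 and −0.16. G530011O06Rik itself had −4.69 and −4.58. Assignment of its reads to Mid1 was argued against too: where 19.2 CPM were lost, Mid1 averaged 0.542 CPM more over the cast groups, at 5.76 CPM in CT, 5.54 in IM and 7.06 in IM-HYA. A variant of the gene itself, from litter or substrain, and an effect of the cast stay open, and neither was tested.

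Clock genes were higher in IM-HYA than in CT by camera, a call lost with an estimated correlation (adjusted p = 0.824). A different phase of the clock at sampling may explain this: Arntl, Clock and Npas2 of the activating arm and Nfil3 had a median log2 fold change of −0.36, with 4 of 4 below 0 but Arntl (−0.25, SE 0.47), Clock (−0.29, SE 0.24) and Nfil3 (−0.44, SE 0.54) near their SE, while the other 16 had a median of 0.72. Colon position as the whole cause was argued against, with a median of 0.50 with that covariate (camera adjusted p = 5.97e-07) and a difference of the list mean between libraries of 0.53 (SE 0.16). RNA quality, for which the 18S share was only a stand-in, stays open. With the 18S share covariate the median was 0.38 (camera adjusted p = 0.000637) and the difference of the list mean was 0.40 (SE 0.20), under 2 SE. The members passing over the list alone went from 6 to 0. The lower activating genes were not confined to IM-HYA. In IM against CT, Arntl, Clock and Npas2 had log2 fold changes of −0.80, −0.59 and −0.91, and Nfil3 0.08. Sampling time, cast and diet cannot be separated here.

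Adipocyte and lymphocyte markers were higher in IM than in CT and lower in IM-HYA than in IM by camera, calls lost with an estimated correlation (adjusted p = 0.489 and 0.683 for adipocyte markers). Tissue attached in IM 3 alone stays open. Without IM 3 the adipocyte medians were 1.04 and −1.32 (camera adjusted p = 8.57e-12 and 1.04e-19). The list mean then differed between libraries by 1.14 and −1.13 (SE 0.55 each). That was just over 2 SE on 5 residual degrees of freedom, too little to decide. Members passing over the list alone went from 13 to 4 and from 13 to 0. IM 1 also lay above the CT libraries in adipocyte markers, at a mean log2 CPM of 4.57 against at most 3.36. Colon position as the whole cause stays open too. With that covariate the median of the rise was 2.13 (camera adjusted p = 9.82e-11, list mean difference 1.68, SE 0.80, 0 members). That difference was just over 2 SE and also fell short of the threshold. For the fall the median was −2.04 (camera adjusted p = 3.07e-18, list mean difference −1.58, SE 0.84, 6 members). A rise in lymphocytes in all IM libraries stays open as well, since 2 of the 3 lay above the highest CT library in T cell markers and IM 2 lay near the floor of that measure; without IM 3 the T cell and B cell medians were 0.65 and 0.37 (camera adjusted p = 0.00381 and 0.239). Fat or lymphoid tissue attached in both IM 1 and IM 3 could account for the pattern, as could an effect of the cast.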
